A study of Homo sapiens with 20 samples.

How the data were processed

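RNA from 20 cultures of the prostate cancer lines C42B and LNCaP was hybridized to Affymetrix 3′ arrays of 54675 probe sets. The groups were C42B with siLSD1 or siNTC (3 arrays each), C42B with DHT or ethanol vehicle (4 each) and LNCaP with siLSD1 or siNTC (3 each). The deposited values are intensities per probe set, made with RMA in the affy package per the submitters' processing notes, whose versions are not given in the sources used here. The deposited intensity values run on a linear scale, from 4.34 to 36333, so log2 was taken of each. Their distributions fall into 3 classes, 1 per experiment, so the arrays were apparently normalized within experiments, and levels were not compared across experiments, except in 1 test of control cells that stayed undecided. The labels name a pair of labelling kits, with 2 µg or 200 ng of RNA, without saying which samples had which, so kit could not be used as a term.

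Of the probe sets, 62 are controls, 41097 name exactly 1 gene, 1801 name several and 11777 name none in the annotation used here. The brightest 1-gene probe set over the 20 arrays stood for each of 19775 genes, and 10523 genes had more than 1. No dim probe set was removed. A group mean of at least 6 on the log2 scale was called bright, and 212, 317 and 599 of the genes called with siLSD1 in C42B, siLSD1 in LNCaP and DHT were dim in both groups. For a named gene with 1 dim group the change was counted from 6 as a lower bound.

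Each comparison was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on its own arrays, without covariates, two-sided, with Benjamini-Hochberg adjustment over the genes. A gene passed at an adjusted p under 0.05. The difference between the lines was tested as a contrast over the 12 siRNA arrays. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. KDM1A was also tested with an exact permutation test. Shared calls were tested with Fisher's exact test against independence, with adjustment over the direction pairs. Its p-values and intervals, and those within strata, treat genes as independent and do not measure the spread between cultures.

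The 21 gene lists were written from general knowledge of these pathways. They were tested with limma's camera at a preset correlation of 0.01 and with the correlation estimated, adjusted over the lists within a comparison. Limma's fry, which tests a list on its own rather than against all other genes, was also planned and run. Every list that passed camera at the preset correlation passed fry as well. Unless fry is named, a list's passing or failing refers to camera, and a list that failed is not shown to be unchanged. Members were counted over all genes and adjusted over the list alone. The lists, the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named KDM1A, the 10 largest rises and 10 largest falls among bright genes that passed and separated the groups completely, and up to 3 passing members per list. It also named the 6 largest differences per direction between the lines and the 6 leading genes per direction pair of shared calls. A gene that the rule named among the falls with siLSD1 in C42B is not reported here. MX1, MX2, OAS2, PSMB9, BAX, SPATA18 and TSC22D3 were named after their values were seen.

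The fit was tested on simulated data in which 200 of 19775 genes changed. Of changes of 0.5 on the log2 scale, 59% were recovered for siLSD1 in C42B, 60% for LNCaP, 79% for DHT and 52% for the difference, and of changes of 1, 96%, 98%, 99% and 94%. False calls numbered 9, 10, 12 and 7. The simulation drew each gene's noise independently and changed far fewer genes than the 11.6% to 32.7% called in the data. The median log2 sizes of the real calls, 0.31 to 0.45, lay below the smallest simulated change. These recovery shares and false calls therefore do not carry over to the real counts.

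The alternatives tried were the mean of all probe sets of a gene, every probe set tested, bright genes only, quantile normalization, median centring, a replicate block, eBayes with trend and robust, arrayWeights, all 20 arrays in 1 fit, and leaving out each array. The replicate numbers did not pair the arrays: treated and control arrays of the same number correlated at −0.096 to 0.20 around their group means, no higher than arrays of other numbers in most cases. Gene families chosen by symbol and odds ratios within strata of brightness and variance were added after seeing the data. The raw array scans were not used here.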

Results

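Gene expression was measured with Affymetrix 3′ arrays in the human prostate cancer line LNCaP and in C42B, a castration-resistant line derived from it. LSD1, the histone lysine demethylase encoded by KDM1A, was targeted with siRNA in both lines (siLSD1) and compared with the control labelled siNTC, with 3 arrays per group. C42B cells were also treated with the androgen dihydrotestosterone (DHT) or with its ethanol vehicle, with 4 arrays per group, which makes 20 arrays in all. The 3 experiments were separate cultures. C42B cells were transfected for 6 h and then kept for 96 h in medium with 10% charcoal-stripped serum (CSS), which is depleted of steroids. LNCaP cells were transfected at 50 nM siRNA and kept for 96 h in 10% fetal bovine serum (FBS). For the androgen experiment, C42B cells spent 72 h in CSS and then 16 h with 100 nM DHT or vehicle. The labels give separate wells for the C42B replicates and pooled pairs of wells for the LNCaP biological replicates. Whether they were independent cultures is not stated, so p-values measure the spread between these samples.

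The deposited intensities had array medians of 78.4 to 81.2 in the C42B siRNA experiment, 84.1 to 86.1 in the androgen experiment and 63.3 to 65.1 in the LNCaP experiment. The distributions separated by experiment, so levels in this part were compared only within an experiment, and the lines were compared through their siRNA effects. Pairs of replicate arrays differed by an SD of 0.133 to 0.212 on the log2 scale, and no pair held the same values throughout. The 3′ minus 5′ log2 signal of the actin control, a sign of RNA integrity and labelling, was 1.17 to 1.31 in C42B siLSD1 and 1.13 to 1.19 in C42B siNTC. In LNCaP it was 0.93 to 1.09 with siLSD1 and 0.82 to 0.98 with siNTC, so the groups overlapped in both lines. The number of arrays limits the precision. A group mean under 6 on the log2 scale was called dim, and for a gene with 1 dim group the change is given as at least its size counted from 6. All other log2 fold changes of genes are those of limma's fit, with its SE where given, and a gene passed at an adjusted p under 0.05 over 19775 genes.

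The KDM1A transcript itself was lower in every array with siLSD1 than in any with siNTC. In C42B its log2 intensity was 7.88 ± 0.12 with siLSD1 and 10.29 ± 0.08 with siNTC (SD, n = 3 each), a fall of 81.1% (log2 fold change −2.40 ± 0.08, limma adjusted p = 1.2e-05). In LNCaP it was 7.30 ± 0.09 with siLSD1 and 10.08 ± 0.14 with siNTC (SD, n = 3 each), a fall of 85.4% (log2 fold change −2.78 ± 0.08, limma adjusted p = 2.4e-06). The two-sided exact permutation p was 0.1 in each line, the smallest that 3 arrays against 3 allow. DHT raised KDM1A slightly in C42B, by 0.16 ± 0.04 on the log2 scale (limma adjusted p = 0.020, exact permutation p = 0.029, the smallest that 4 against 4 allow). KDM1A was read by 1 probe set.

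**Figure D1:**
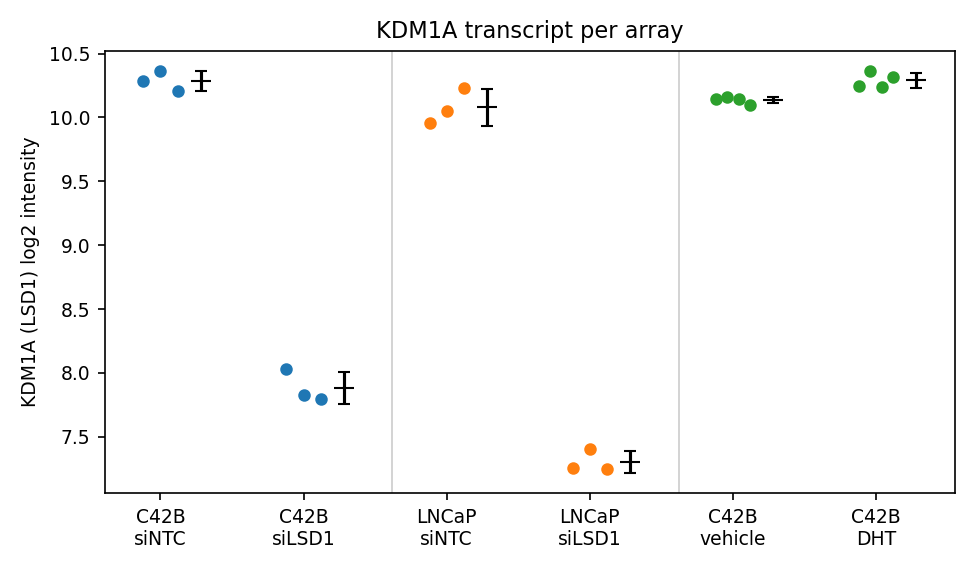
KDM1A log2 intensity (vertical axis) of each array in the 6 groups, with the group mean and SD (n = 3 for siRNA groups, n = 4 for DHT and vehicle) beside the points. The siLSD1 arrays lie near 7.88 in C42B and 7.30 in LNCaP, below all siNTC arrays, which lie near 10.29 and 10.08, and levels are comparable only within an experiment.

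The siLSD1 and siNTC arrays of C42B address which transcripts change in these cells with siLSD1 in steroid-depleted medium. Each line has a single siLSD1 label, so effects of the siRNA's sequence cannot be told apart from those of lower LSD1. This holds for every siLSD1 result here, changes shared by the lines included. ACP3, prostatic acid phosphatase, rose 3.93-fold (log2 fold change 1.97 ± 0.05, n = 3 per group, adjusted p = 1.1e-05). The other leading rises were TMEM178A (1.76 ± 0.10), PROCR, the endothelial protein C receptor (1.70 ± 0.10), SERPINI1, neuroserpin (1.69 ± 0.05), PTBP2, a neuronal splicing regulator (1.66 ± 0.09), DNASE1L3 (1.66 ± 0.07) and RTN1 (1.61 ± 0.08). From dim controls, the tetraspanins TSPAN8 and TSPAN7 rose by at least 0.67 and 1.58 on the log2 scale and the sodium channel subunit SCN4B by at least 1.24. After KDM1A, the largest fall was that of IGFBP3, which binds insulin-like growth factors (log2 fold change −1.5 ± 0.06, adjusted p = 2.3e-05). It was followed by the fatty acid carrier FABP5 (−1.24 ± 0.06), the growth factor IGF1 (−1.18 ± 0.06) and the liver glycogen phosphorylase PYGL (−1.17 ± 0.10). Further falls were those of NAV3 (−1.0 ± 0.08), PLPPR1 (−0.93 ± 0.05) and UGT2B15 (−0.87 ± 0.07), an androgen-conjugating enzyme. RUNDC3B fell by at least 0.51, to a dim level. UGT2B15, UGT2B17 and UGT2B28 are paralogs of similar sequence, so the signal of a probe set may not belong to a single gene.

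In all, 1713 genes were higher and 1856 lower with siLSD1 in C42B, with a median change of 0.32 in log2 size. Most changes were small: 43 genes rose and 6 fell at least 2-fold. Single arrays changed these counts. Leaving out siLSD1 replicate 3 left 958 higher and 949 lower genes, of which 942 and 937 were also called with all arrays. Leaving out siLSD1 replicate 2 left 1013 and 1098, while leaving out siLSD1 replicate 1 gave 1975 and 1987. The lower genes numbered 1147 without siNTC replicate 2 and 1183 without siNTC replicate 3.

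Cell division genes fell together in C42B. Of 35 mitosis genes 29 fell and none rose (31 fell when adjusted over the list alone), with a median log2 fold change of −0.44. Examples are the spindle protein ASPM (−0.82 ± 0.06), the kinetochore protein CENPF (−0.67 ± 0.05) and DLGAP5 (−0.64 ± 0.05). Of 34 measured DNA replication genes 26 fell and none rose (29 adjusted over the list alone). Among them were MCM2 (−0.61 ± 0.05), MCM5 (−0.53 ± 0.06) and CDC45 (−0.50 ± 0.06). In the test against all other genes (camera) the adjusted p was 5.2e-20 for mitosis and 9.3e-15 for replication, but adjusted p = 0.13 and adjusted p = 0.14 with an estimated correlation. MYC and ribosome biogenesis genes fell as well, with 7 of 20 lower and none higher (8 adjusted over the list alone). Among them were MYC (−0.41 ± 0.06), FBL (−0.26 ± 0.05) and NOP58 (−0.25 ± 0.06). Their adjusted p was 3.7e-04, and adjusted p = 0.14 with an estimated correlation. Hypoxia and glycolysis genes fell in 12 of 23 cases and rose in 1 (14 and 1 adjusted over the list alone), led by the phosphofructokinase regulators PFKFB3 (−0.75 ± 0.05) and PFKFB4 (−0.54 ± 0.09) and the prolyl hydroxylase EGLN3 (−0.72 ± 0.07). Their adjusted p was 6.3e-05, and adjusted p = 0.34 with an estimated correlation.

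Among genes known to be induced by androgens, more rose than fell with siLSD1 in C42B, in a medium without added androgen. Of 40 measured, 20 rose and 3 fell (22 and 3 adjusted over the list alone), with a median of 0.26 and adjusted p = 1.1e-10, but adjusted p = 0.10 with an estimated correlation. The largest rises were those of the ion channel TRPM8 (1.5 ± 0.05), the prostate transporter SLC45A3 (1.19 ± 0.06) and the transcription factor MAF (1.06 ± 0.06). Of 10 androgen-repressed genes 2 rose and 3 fell (2 and 4 adjusted over the list alone, adjusted p = 0.53), among them UGT2B15, UGT2B17 (a fall of at least 0.29) and DDC, which makes dopamine (0.55 ± 0.05). Endoplasmic reticulum (ER) chaperone genes rose in 10 of 19 cases with none lower (11 adjusted over the list alone). Among them were PDIA3 (0.65 ± 0.08), DNAJC3 (0.55 ± 0.06) and DNAJB9 (0.51 ± 0.06). This list had adjusted p = 2.2e-06, and adjusted p = 0.10 with an estimated correlation. Fatty acid synthesis genes rose in 7 of 14 cases with none lower (9 adjusted over the list alone). Among them were the elongases ELOVL7 (0.60 ± 0.05) and ELOVL5 (0.43 ± 0.05) and the acyl-CoA synthetase ACSL1 (0.50 ± 0.05). The adjusted p was 4.2e-05, and adjusted p = 0.14 with an estimated correlation. Luminal epithelial genes rose in 5 of 18 cases with none lower (5 adjusted over the list alone, adjusted p = 0.0047, and adjusted p = 0.14 with an estimated correlation), among them OVOL1 (0.34 ± 0.05), OCLN (0.33 ± 0.05) and KRT19 (0.32 ± 0.07). The p53 target list had 6 higher and 3 lower of 21 (8 and 3 adjusted over the list alone, adjusted p = 0.0081, and adjusted p = 0.21 with an estimated correlation). RRM2B (0.73 ± 0.11), GADD45A (0.52 ± 0.08) and GDF15 (0.50 ± 0.06) were higher. With the mean of all probe sets per gene neither the p53 list (adjusted p = 0.11) nor GDF15 (0.16, adjusted p = 0.13) passed.

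Together with the androgen-repressed genes, 12 lists failed camera's test in C42B, at an adjusted p of 0.093 to 0.92 and adjusted p = 0.21 to 0.94 with an estimated correlation. By fry, which tests a list on its own, polyamine (adjusted p = 0.0019), interferon-stimulated and amino acid response genes (both 0.0027) passed. Cholesterol synthesis (fry adjusted p = 0.016) and androgen-repressed genes (0.044) passed fry as well, and the rest of these lists failed it. Cholesterol synthesis genes were higher in 6 of 18 cases (7 and 1 adjusted over the list alone, adjusted p = 0.093), among them SC5D (0.37 ± 0.04), HMGCS1 (0.32 ± 0.08) and STARD4 (0.28 ± 0.05). With the mean of all probe sets SC5D (0.092, adjusted p = 0.24) and HMGCS1 (0.072, adjusted p = 0.64) no longer passed, and the list itself passed without siLSD1 replicate 1 or without siNTC replicate 2 (adjusted p = 0.049 and adjusted p = 0.048). Interferon-stimulated genes had 7 higher and 3 lower of 28 (7 and 3 adjusted over the list alone, adjusted p = 0.095). IFIT1 (at least 0.80) and IFI6 (0.71 ± 0.07) passed higher and OAS3 (−0.45 ± 0.05) lower. The list passed with the mean of all probe sets (adjusted p = 0.043). Amino acid response genes, targets of ATF4, had 1 higher and 6 lower of 24 (3 and 10 adjusted over the list alone, adjusted p = 0.14). VLDLR (−0.45 ± 0.07), MTHFD2 (−0.42 ± 0.05) and PCK2 (−0.37 ± 0.06) were lower. The list passed with the mean of all probe sets (adjusted p = 0.033). Polyamine genes had 4 higher and 3 lower of 13 (4 and 3 adjusted over the list alone, adjusted p = 0.80). The arginase ARG2 (1.49 ± 0.05), SAT2 (0.37 ± 0.05) and SAT1 (0.36 ± 0.07) were higher. Partners and relatives of LSD1 had 2 higher and 2 lower of 23 (4 and 3 adjusted over the list alone, adjusted p = 0.92). ZNF217 (0.43 ± 0.09) and REST (0.27 ± 0.07) passed higher and CTBP1 (−0.32 ± 0.05) lower. Neuronal and neuroendocrine genes had 1 higher and 3 lower of 26 (1 and 3 adjusted over the list alone, adjusted p = 0.89). SCG5 (at least 0.11) passed higher and ENO2 (−0.32 ± 0.06) and CHGB, dim in both groups, lower. Immediate early genes had 1 higher and 2 lower of 17 (1 and 2 adjusted over the list alone, adjusted p = 0.89), with DUSP1 (0.28 ± 0.06), IER2 (−0.27 ± 0.05) and KLF2 (−0.26 ± 0.06). NRF2 antioxidant genes had 2 higher and 2 lower of 13 (4 and 4 adjusted over the list alone, adjusted p = 0.89), with ME1 (0.35 ± 0.05), PGD (0.25 ± 0.06) and TXNRD1 (−0.19 ± 0.05). Of 18 mesenchymal genes (0 and 1 adjusted over the list alone, adjusted p = 0.89) 1 fell, LOX, dim in both groups. None of 7 basal epithelial genes (0 and 0 adjusted over the list alone, adjusted p = 0.52) passed (KRT5, with a dim siLSD1 group, adjusted p = 0.25), and none of 12 markers of stromal, endothelial and leukocyte cells passed (0 and 0 adjusted over the list alone, adjusted p = 0.89), the largest change being that of COL3A1 (−0.27 ± 0.10, adjusted p = 0.11). COL3A1 passed with the replicate block (limma adjusted p = 0.048). Among the genes named for C42B, CHGB, CLEC7A, DUSP1, FBL, HMGCS1, KLF2, KRT19, NOP58, PGD, REST, S100P, TXNRD1 and ZNF217 no longer passed without siLSD1 replicate 3. With the mean of all probe sets the calls of DUSP1, KRT19, LOX, PGD, REST and TXNRD1 ended as well. For the polyamine, mesenchymal and NRF2 lists the median, mean and test differed in sign.

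In LNCaP the siLSD1 and siNTC arrays ask the same question in serum-containing medium. Interferon-induced genes were among the leading rises. IFIT1 rose 5.86-fold (log2 fold change 2.55 ± 0.09, n = 3 per group, adjusted p = 4.1e-06), OASL by 2.16 ± 0.06, HERC5 by 2.04 ± 0.10 and IFIT2 by 2.02 ± 0.10. The calcium-binding protein S100P rose by 2.48 ± 0.07, HMGN2P46, a pseudogene resembling HMGN2, by 2.43 ± 0.08 and PTBP2 by 2.28 ± 0.11. From dim controls, the chondroitin sulfate enzyme CSGALNACT1 rose by at least 2.03, the chemokine CXCL10 by at least 1.96 and the potassium channel subunit KCNG3 by at least 1.51. After KDM1A the largest falls between bright groups were those of UGT2B28 (−2.40 ± 0.08, adjusted p = 3.1e-06) and the mitotic kinesins KIF14 (−2.01 ± 0.08) and KIF15 (−1.78 ± 0.10). The Mediator kinase CDK19 (−1.90 ± 0.06), TMX1 (−1.89 ± 0.19) and the cell cycle repressor E2F7 (−1.84 ± 0.14) were also among them. Falls to a dim level were those of ID1 (at least 1.59), the transcription factor MYBL1 (at least 1.53) and CCDC83 (at least 1.45). A second probe set of CDK19 changed the other way (0.33, adjusted p = 0.023). In all, 2640 genes were higher and 2480 lower with siLSD1 in LNCaP, with a median change of 0.39 in log2 size, and 131 rose and 204 fell at least 2-fold.

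All 35 mitosis genes fell in LNCaP (35 adjusted over the list alone), with a median log2 fold change of −1.21, including CDC20 (−1.62 ± 0.07), ASPM (−1.59 ± 0.13) and TOP2A (−1.58 ± 0.11). Of 34 DNA replication genes 32 fell and none passed higher (32 lower and 1 higher adjusted over the list alone), with a median of −0.93. Among them were MCM10 (−1.51 ± 0.06), UHRF1 (−1.47 ± 0.11) and TYMS (−1.47 ± 0.06). The adjusted p was 1.9e-33 for mitosis and 1.9e-26 for replication, and adjusted p = 0.17 and adjusted p = 0.14 with an estimated correlation. MYC and ribosome biogenesis genes fell in 15 of 20 cases with none higher (16 adjusted over the list alone), with NOP58 at −0.63 ± 0.07, MYC at −0.56 ± 0.06 and UTP20 at −0.49 ± 0.11. Their adjusted p was 4.3e-08, and adjusted p = 0.17 with an estimated correlation. Interferon-stimulated genes rose in 17 of 28 cases and fell in 2 (19 and 2 adjusted over the list alone), with a median of 0.74, adjusted p = 3.6e-09, and adjusted p = 0.17 with an estimated correlation. Within that list OAS3 (−0.53) and PSMB9 (−0.32) fell, while MX1 (0.02) and MX2 and OAS2, both dim in both groups, did not pass. None of 12 stromal, endothelial and leukocyte markers, 8 of them dim in both groups, rose beside them (0 and 1 adjusted over the list alone, camera adjusted p of the list = 0.82). Of these markers 1, COL3A1, passed lower (−0.77 ± 0.13).

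Androgen-induced genes rose in 22 of 40 cases and fell in 6 in LNCaP (22 and 6 adjusted over the list alone), with a median of 0.24. They were led by TRPM8 (1.88 ± 0.06), the prostaglandin dehydrogenase HPGD (1.28 ± 0.14) and ALDH1A3 (1.27 ± 0.07). Their adjusted p was 5.3e-04, and adjusted p = 0.26 with an estimated correlation. Androgen-repressed genes went both ways, 4 higher and 4 lower of 10 (4 and 4 adjusted over the list alone, adjusted p = 0.29). UGT2B28 and UGT2B15 (−1.57 ± 0.07) passed lower and the steroid-converting enzyme AKR1C3 (at least 1.64) higher. The remaining passing lists were fatty acid synthesis genes (5 of 14 higher, none lower), ER chaperone genes (6 of 19 higher, 1 lower) and luminal epithelial genes (5 of 18 higher, none lower). Adjusted over the list alone these were 5, then 7 with 1 lower, then 5. Examples are ELOVL7 (0.82 ± 0.06), ACACA (0.43 ± 0.06) and SCD (0.36 ± 0.06), then DNAJB9 (0.86 ± 0.07), EDEM1 (0.73 ± 0.06) and DNAJC3 (0.57 ± 0.06), then KRT19 (1.34 ± 0.09), OCLN (0.87 ± 0.06) and OVOL1 (0.84 ± 0.07). Their adjusted p values were 0.022, 0.0091 and 0.0091, with adjusted p = 0.37, adjusted p = 0.26 and adjusted p = 0.26 with an estimated correlation. Without siNTC replicate 1 none of these 3 lists passed (adjusted p = 0.15, 0.059 and 0.066).

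The other lists failed camera's test in LNCaP, at an adjusted p of 0.26 to 0.84 and adjusted p = 0.66 to 0.92 with an estimated correlation. Among lists that failed camera, androgen-repressed (fry adjusted p = 8.6e-04), p53 target (0.014) and polyamine genes (0.018) passed fry, and the rest failed it. Cholesterol synthesis genes had 5 higher and 4 lower of 18 (5 and 4 adjusted over the list alone, adjusted p = 0.84). INSIG1 (−0.90 ± 0.14) and EBP (−0.47 ± 0.07) passed lower and STARD4 (0.56 ± 0.09) higher. The p53 targets had 4 higher and 7 lower of 21 (4 and 7 adjusted over the list alone, adjusted p = 0.26). DDB2 (−0.73 ± 0.06), TRIAP1 (−0.66 ± 0.05) and ZMAT3 (−0.61 ± 0.10) were lower. Amino acid response genes had 4 higher and 7 lower of 24 (5 and 8 adjusted over the list alone, adjusted p = 0.72). MTHFD2 (−0.96 ± 0.06) passed lower and SLC7A11 (0.86 ± 0.07) and NUPR1 (0.42 ± 0.07) higher. A second probe set of SLC7A11 changed the other way (−0.25, adjusted p = 0.048). Hypoxia and glycolysis genes had 3 higher and 5 lower of 23 (5 and 5 adjusted over the list alone, adjusted p = 0.72). EGLN3 (−0.48 ± 0.13) and ADM (−0.41 ± 0.10) passed lower and SLC2A1 (0.38 ± 0.06) higher. LSD1 partners and relatives had 4 higher and 5 lower of 23 (4 and 5 adjusted over the list alone, adjusted p = 0.79). HDAC2 (−0.51 ± 0.07), CHD4 (−0.48 ± 0.08) and MTA2 (−0.40 ± 0.10) were lower. NRF2 genes had 4 higher and 2 lower of 13 (4 and 2 adjusted over the list alone, adjusted p = 0.79). TXNRD1 (−0.94 ± 0.06) passed lower and SRXN1 (0.31 ± 0.06) higher. Polyamine genes had 4 higher and 2 lower of 13 (4 and 2 adjusted over the list alone, adjusted p = 0.72). SAT1 (0.65 ± 0.06) and SAT2 (0.36 ± 0.06) passed higher and ODC1 (−0.38 ± 0.05) lower. Immediate early genes had 1 higher and 3 lower of 17 (1 and 3 adjusted over the list alone, adjusted p = 0.79), with EGR1 (a rise of at least 0.32), JUNB (−0.36 ± 0.07) and ATF3 (−0.25 ± 0.06). Of 26 neuronal and neuroendocrine genes (0 and 1 adjusted over the list alone, adjusted p = 0.79) UCHL1 (−0.47 ± 0.09) and TUBB3 (−0.24 ± 0.07) fell. Of 18 mesenchymal genes (1 and 1 adjusted over the list alone, adjusted p = 0.79) ITGA5 (0.36 ± 0.09) rose and FN1 (−0.35 ± 0.06) fell. Of 7 basal genes (1 and 1 adjusted over the list alone, adjusted p = 0.72) KRT14, dim in both groups, rose and S100A2 (−0.42 ± 0.10) fell. ADM, ATF3, DPYSL5, EGLN3, ITGA5, LHX6, MTA2, NOS3, S100A2, TUBB3 and UTP20 no longer passed in LNCaP without at least 1 of the arrays. With the mean of all probe sets the calls of ATF3 and DNAJC3 ended. For the neuronal, stromal and immediate early lists the median, mean and test differed in sign.

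**Figure D2:**
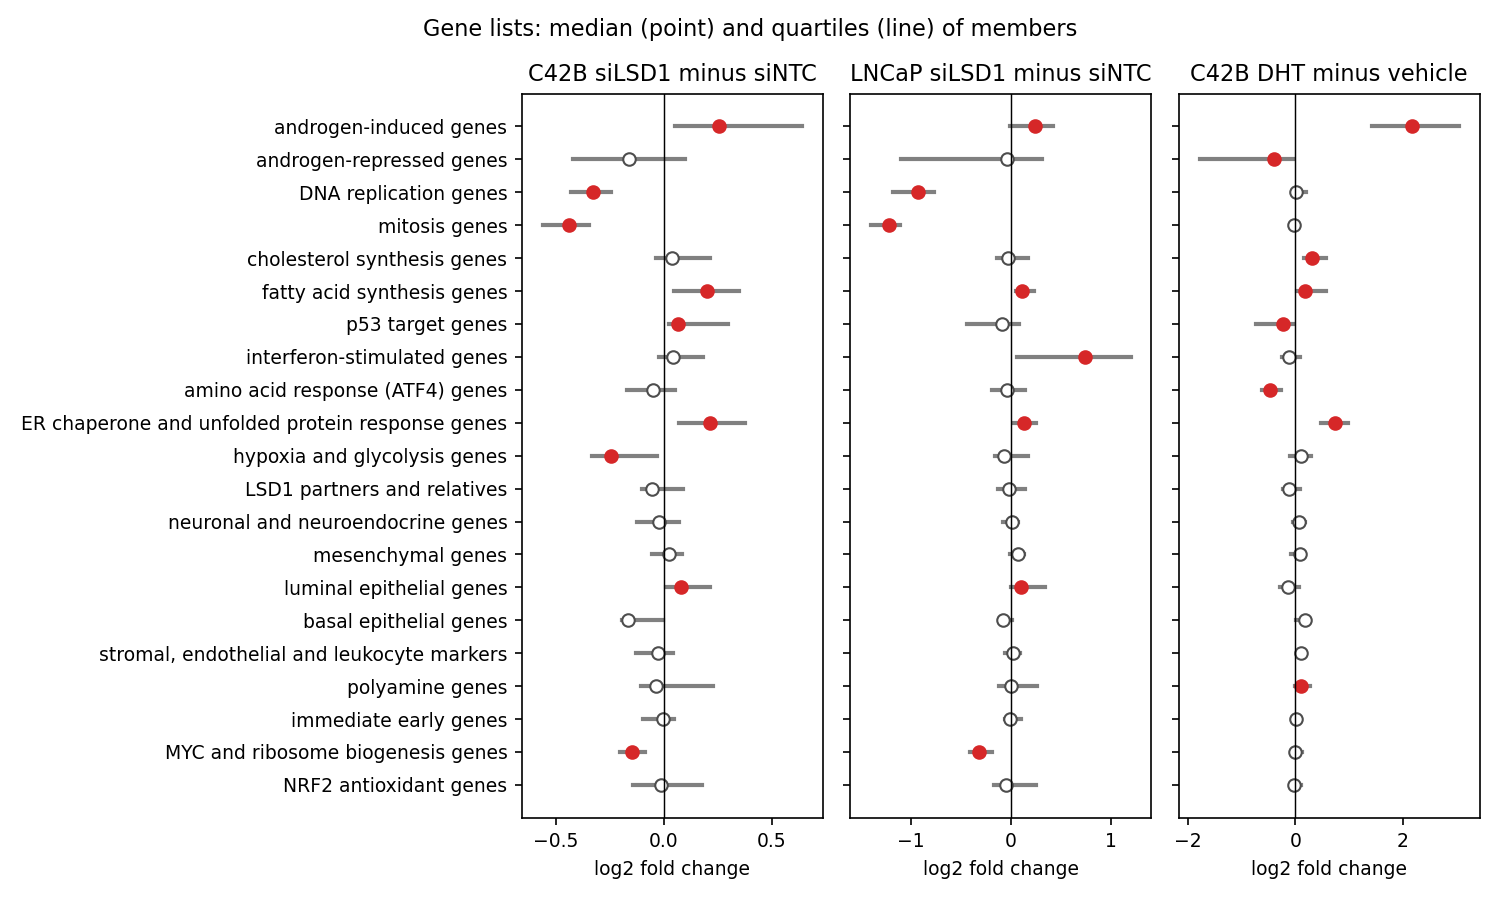
Median log2 fold change (points) and quartiles (lines) of the measured members of 21 gene lists in 3 comparisons, with siLSD1 minus siNTC in C42B and LNCaP and DHT minus vehicle in C42B. Horizontal axes differ between panels, and filled red points mark lists past camera's test at an adjusted p under 0.05 with the preset correlation. Mitosis genes lie at −0.44 in C42B and −1.21 in LNCaP with siLSD1, and androgen-induced genes at 2.17 with DHT.

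Many of the same genes changed in both lines. ACP3 rose by 1.97 ± 0.05 in C42B and 1.80 ± 0.07 in LNCaP, PTBP2 by 1.66 ± 0.09 and 2.28 ± 0.11, HMGN2P46 by 1.5 ± 0.08 and 2.43 ± 0.08, TRPM8 by 1.5 ± 0.05 and 1.88 ± 0.06, SERPINI1 by 1.69 ± 0.05 and 1.47 ± 0.07, and TSPAN7, from dim controls, by at least 1.58 and 1.33. Besides KDM1A, the leading shared falls were those of UGT2B15 (−0.87 ± 0.07 and −1.57 ± 0.07), QSER1 (−0.82 ± 0.06 and −1.06 ± 0.06) and ASPM (−0.82 ± 0.06 and −1.59 ± 0.13), and those of IGF1 (−1.18 ± 0.06 in C42B) and NAV3 (−1.0 ± 0.08 in C42B), which fell to a dim level in LNCaP by at least 0.30 and 1.33. In all, 1047 genes were higher in both lines where independent lists would share 229 (Fisher's exact test, odds ratio 16.3, 95% interval 14.5 to 18.2), and 1116 were lower in both where 233 would be shared (odds ratio 18.3, 16.4 to 20.4). These experiments share no arrays. The intervals treat genes as independent, which they are not, so they do not measure the spread between cultures. Without C42B siLSD1 replicate 3 these counts were 670 and 696. Of 2227 genes that passed in both lines, 97.1% went the same way. Across all genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.58 and a Spearman correlation of 0.46.

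Opposite changes were rare, at 25 genes higher in C42B and lower in LNCaP (215 if independent) and 39 the other way (248 if independent). PYGL fell by 1.17 in C42B and rose by 0.67 ± 0.08 in LNCaP. The interferon-induced IFITM1 was at −0.66 ± 0.07 in C42B and 1.11 ± 0.10 in LNCaP, and S100P at −0.32 ± 0.06 and 2.48 ± 0.07. HBQ1 (−0.55 ± 0.07 and 0.57 ± 0.11), DPYSL5 (−0.34 ± 0.06 and 0.38 ± 0.09) and LHX6 (−0.32 ± 0.06 and a rise of at least 0.24) went the same way as these, but with the mean of all probe sets DPYSL5 (adjusted p = 0.088) and LHX6 (adjusted p = 0.22) no longer passed in LNCaP. In the other direction were CLEC7A (0.44 ± 0.09 in C42B and −1.01 ± 0.13 in LNCaP), STOX2 (0.56 ± 0.08 and −0.82 ± 0.09), CNTNAP2 (0.42 ± 0.07 and −0.70 ± 0.16), GBP2 (0.53 ± 0.08 and −0.57 ± 0.09), NXPE3 (0.44 ± 0.08 and −0.50 ± 0.10) and NOS3 (0.42 ± 0.05 and a fall of at least 0.39). CNTNAP2 no longer passed in C42B with the mean of all probe sets (0.16, adjusted p = 0.13). These small counts moved with single arrays, from 13 without C42B siLSD1 replicate 2 or 3 to 49 without replicate 1 for the 25 genes, and from 12 without siLSD1 replicate 2 or 3 to 45 without LNCaP siNTC replicate 1 for the 39. With all 20 arrays in 1 fit they were 47 and 63, and with median centring the 39 became 22.

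**Figure D3:**
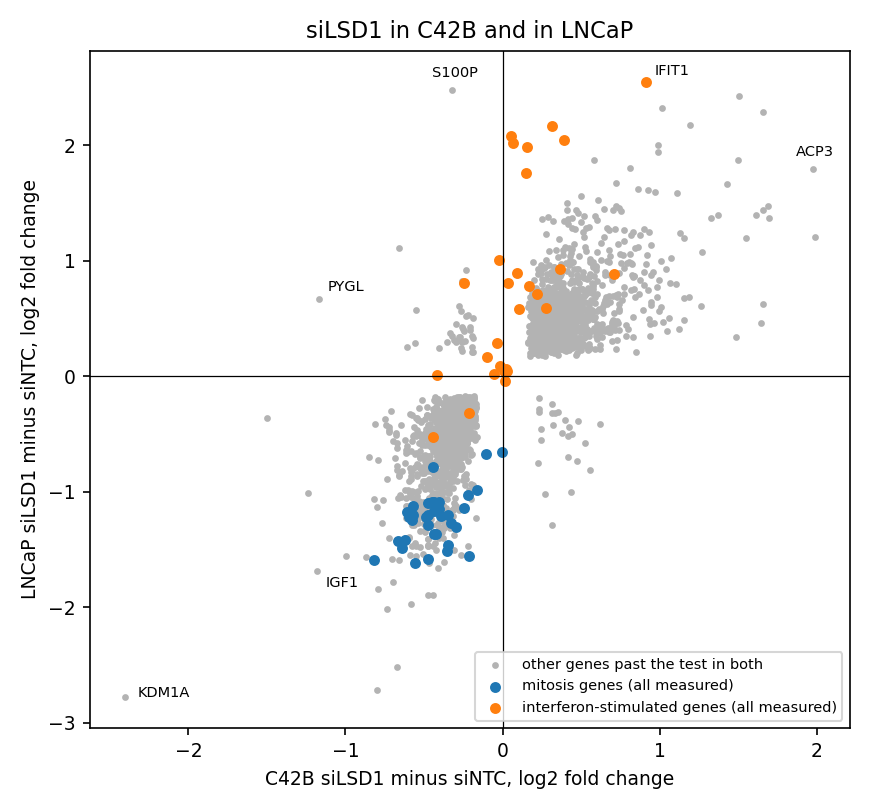
Log2 fold change with siLSD1 in C42B (horizontal axis) against LNCaP (vertical axis), each from 3 siLSD1 and 3 siNTC arrays. Grey points are genes past the test in both lines, and colored points all measured mitosis genes (35) and interferon-stimulated genes (28). Mitosis genes lie low on the vertical axis (median −1.21 against −0.44) and several interferon genes lie high on it with little change in C42B.

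The size of the siLSD1 effect was compared between the lines as the C42B effect minus the LNCaP effect. The effect in C42B lay above that in LNCaP for 1100 genes and below it for 1200, with a difference of at least 2-fold for 58 and 46. With arrayWeights 1726 genes lay above and 1831 below. Line, medium, transfection protocol, and normalization all changed together between the experiments, so the difference is one between experiments. The labelling kit may differ too, and the siRNA dose in C42B is not in the labels. Of 100 splits of the siRNA labels within each line, the real one included, 6 gave as many genes. Such splits keep or mix the siRNA effect of each line, so they cannot decide whether the lines differ. Of the genes named for a positive difference, TM4SF1 (1.60 ± 0.08, adjusted p = 2.8e-07) and ZNF367 (1.52 ± 0.16) were bright in all groups. UGT2B28, CCDC83, MYBL1 and TMEM178A also passed above, but UGT2B28 had a dim siLSD1 group in C42B, CCDC83 and MYBL1 had one in LNCaP and TMEM178A was dim in both LNCaP groups, so their differences have no exact size. The largest negative differences between bright groups were those of S100P (−2.80 ± 0.09, adjusted p = 1.5e-08), IFIT2 (−1.95 ± 0.24), OASL (−1.85 ± 0.08) and PYGL (−1.84 ± 0.13). CXCL10 and RSAD2 also passed below, but were dim in both C42B groups, so their differences are not measured on both sides.

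All 35 mitosis genes and 28 of 34 DNA replication genes fell less in C42B than in LNCaP (35 and 29 adjusted over the list alone), with median differences of 0.77 and 0.58. Interferon-stimulated genes were lower in the C42B effect in 15 of 28 cases with none higher (18 adjusted over the list alone), with a median difference of −0.48. The p53 targets had 7 of 21 above and none below (11 and 1 adjusted over the list alone), with a median difference of 0.22, led by ZMAT3 (0.80), BAX (0.56) and SPATA18 (0.52). In the order given, the adjusted p was 4.5e-40, 8.4e-28, 3.8e-13 and 7.0e-06, and adjusted p = 0.033, 0.012, 0.0082 and 0.033 with an estimated correlation. MYC and ribosome biogenesis genes had 4 of 20 above and none below (5 adjusted over the list alone, median difference 0.16, adjusted p = 3.8e-04, and adjusted p = 0.15 with an estimated correlation). Hypoxia and glycolysis genes had 5 of 23 below and none above (8 and 1 adjusted over the list alone, median difference −0.21, adjusted p = 0.0018, and adjusted p = 0.50 with an estimated correlation). The other 15 lists did not pass, at an adjusted p of 0.066 to 0.89, among them the androgen-induced genes with 12 above and 7 below of 40 (18 and 11 adjusted over the list alone, adjusted p = 0.066, and adjusted p = 0.50 with an estimated correlation) and the luminal genes with 5 of 18 below (5 adjusted over the list alone, adjusted p = 0.066, and adjusted p = 0.34 with an estimated correlation). Both of these lists passed with the mean of all probe sets (adjusted p = 0.030 and 0.038). The androgen-induced list also passed without LNCaP siNTC replicate 1 (adjusted p = 0.017), and the luminal list with quantile normalization (adjusted p = 0.011) and in 4 of the fits that left out 1 array (adjusted p = 0.025 to 0.0496). By fry, luminal (adjusted p = 0.0015), androgen-repressed (0.0097), polyamine (0.021) and androgen-induced genes (0.026) passed among these 15 lists, and the rest failed. For the fatty acid, ER chaperone, neuronal, immediate early and stromal lists the median, mean and test differed in sign.

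DHT against vehicle in C42B asks which transcripts respond to the androgen itself. Between bright groups, the kallikrein protease KLK2 rose by 5.19 ± 0.06 on the log2 scale (n = 4 per group, adjusted p = 7.5e-11), CSGALNACT1 by 4.44 ± 0.06, the sialyltransferase ST6GALNAC1 by 4.03 ± 0.05 and SLC45A3 by 3.83 ± 0.09. From a dim vehicle group, the transcription factor SNAI2 rose by at least 4.1 (adjusted p = 1.7e-10), with a mean log2 intensity of 10.14 with DHT, and TRPM8 by at least 3.86. Other such rises were those of the metalloreductase STEAP4 (at least 3.51), CCDC141 (at least 2.89), CTNNA2 (at least 2.84) and LINC00844 (at least 1.97). The largest falls between bright groups were those of SYTL2 (−3.20 ± 0.05, adjusted p = 2.0e-10), LRRN1 (−3.20 ± 0.07), the chemokine receptor ACKR3 (−3.14 ± 0.06), MATN2 (−2.75 ± 0.09) and FOXQ1 (−2.71 ± 0.06). AMIGO2 fell to a dim level by at least 2.91 (adjusted p = 7.5e-11), the phosphatase PTPRR by at least 2.86, CSRNP3 by at least 1.8, PGR, the progesterone receptor, by at least 1.63 and CCDC83 by at least 1.25. In all, 2643 genes were higher and 3827 lower with DHT, with a median change of 0.31 in log2 size. Of these 230 rose and 231 fell at least 2-fold, and 62 and 32 at least 4-fold.

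Of 40 measured androgen-induced genes 39 rose (39 adjusted over the list alone), with a median of 2.17, adjusted p = 2.2e-40, and adjusted p = 1.6e-04 with an estimated correlation. The exception was TSC22D3 (−0.75). Androgen-repressed genes fell in 5 of 10 cases with none higher (5 lower and 1 higher adjusted over the list alone, adjusted p = 0.0039, and adjusted p = 0.068 with an estimated correlation), led by ACKR3, UGT2B17 (a fall of at least 1.18) and UGT2B15 (−2.09 ± 0.11). ER chaperone and unfolded protein response genes rose in 18 of 19 cases (18 adjusted over the list alone), with a median of 0.73. Among them were DNAJB9 (1.64 ± 0.04), DNAJC3 (1.14 ± 0.05) and MANF (1.12 ± 0.04). Camera gave adjusted p = 4.4e-16, and adjusted p = 0.010 with an estimated correlation. Amino acid response genes fell in 21 of 24 cases and rose in 1 (21 and 1 adjusted over the list alone), with a median of −0.48. Among them were STC2 (−1.06 ± 0.04), CHAC1 (−1.04 ± 0.07) and SLC7A11 (−0.83 ± 0.05). This list had adjusted p = 7.3e-11, and adjusted p = 0.051 with an estimated correlation. Cholesterol synthesis genes rose in 14 of 18 cases and fell in 2 (15 and 2 adjusted over the list alone), with IDI1 (0.80 ± 0.04), HMGCS1 (0.71 ± 0.06) and INSIG1 (0.62 ± 0.07). The adjusted p was 4.2e-06, and adjusted p = 0.051 with an estimated correlation. Fatty acid synthesis genes rose in 8 of 14 cases and fell in 2 (9 and 2 adjusted over the list alone), with ELOVL7 (1.44 ± 0.05) and ELOVL5 (0.89 ± 0.04) higher and ELOVL6 (−0.69 ± 0.06) lower. Camera gave adjusted p = 0.0041, and adjusted p = 0.068 with an estimated correlation. Polyamine genes rose in 6 of 13 cases and fell in 1 (7 and 1 adjusted over the list alone), with SAT1 (1.61 ± 0.04), SMS (1.02 ± 0.05) and ODC1 (0.81 ± 0.04). This list had adjusted p = 0.0040, and adjusted p = 0.051 with an estimated correlation. The p53 targets fell in 12 of 21 cases and rose in 4 (13 and 4 adjusted over the list alone), with GADD45A (−1.38 ± 0.05), the death receptor FAS (−1.22 ± 0.06) and TP53INP1 (−0.96 ± 0.05). The adjusted p was 0.0039, and adjusted p = 0.051 with an estimated correlation.

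The other lists failed camera's test with DHT, at an adjusted p of 0.11 to 0.71 and adjusted p = 0.28 to 0.85 with an estimated correlation. By fry, LSD1 partners (adjusted p = 4.3e-06), mesenchymal (8.2e-06), hypoxia and glycolysis (1.7e-05) and NRF2 genes (4.5e-05) passed. Basal, immediate early (both fry adjusted p = 0.0077) and DNA replication genes (0.034) also passed fry. The mitosis, interferon, neuronal, luminal, stromal and MYC lists failed it. DNA replication genes had 11 higher and 4 lower of 34 (11 and 5 adjusted over the list alone, adjusted p = 0.21). CDC6 (0.52 ± 0.04), RRM2 (0.39 ± 0.04) and GINS3 (0.32 ± 0.05) were higher. Mitosis genes had 3 higher and 3 lower of 35 (2 and 1 adjusted over the list alone, adjusted p = 0.46), with KIF20A (0.27 ± 0.04), CCNA2 (−0.21 ± 0.07) and BUB1B (−0.19 ± 0.04). Hypoxia and glycolysis genes had 9 higher and 4 lower of 23 (10 and 5 adjusted over the list alone, adjusted p = 0.11). NDRG1 (3.24 ± 0.04), ANKRD37 (1.75 ± 0.04) and HK2 (0.89 ± 0.05) were higher. The list passed without DHT replicate 3 (adjusted p = 0.036) and among brighter genes (adjusted p = 0.046). Interferon-stimulated genes had 3 higher and 10 lower of 28 (3 and 11 adjusted over the list alone, adjusted p = 0.29). HERC5 (1.83 ± 0.06) passed higher and CMPK2 (−1.06 ± 0.08) and IFIT1 (at least 0.06) lower. LSD1 partners and relatives had 3 higher and 10 lower of 23 (3 and 10 adjusted over the list alone, adjusted p = 0.21). KDM1B (−0.57 ± 0.07) passed lower and MTA2 (0.42 ± 0.07) higher. The brightest probe set of CTBP1 fell (−1.06 ± 0.04) while another rose (1.09, adjusted p = 2.8e-07), so the gene has no single direction here. Luminal genes had 4 higher and 9 lower of 18 (4 and 10 adjusted over the list alone, adjusted p = 0.41). The keratins KRT19 (at least 1.76) and KRT8 (1.38 ± 0.05) passed higher and OCLN (−0.91 ± 0.05) lower. Mesenchymal genes had 3 higher and 1 lower of 18 (2 and 1 adjusted over the list alone, adjusted p = 0.24). SNAI2 and LOX (at least 1.33) passed higher and VIM (−0.46 ± 0.06) lower. Of 26 neuronal and neuroendocrine genes (1 and 3 adjusted over the list alone, adjusted p = 0.47) 2 rose and 4 fell, with ENO2 (−0.63 ± 0.08), VGF (0.44 ± 0.06) and FOXA2, which passed higher while dim in both groups. Immediate early genes had 4 higher and 1 lower of 17 (4 and 0 adjusted over the list alone, adjusted p = 0.38), with NR4A1 (0.71 ± 0.05), ZFP36 (0.50 ± 0.04) and DUSP1 (0.17 ± 0.05). MYC and ribosome biogenesis genes had 5 higher and 3 lower of 20 (7 and 3 adjusted over the list alone, adjusted p = 0.71), with MYC (−0.35 ± 0.04), WDR12 (−0.28 ± 0.04) and NOP16 (0.27 ± 0.04). NRF2 genes had 2 higher and 3 lower of 13 (2 and 3 adjusted over the list alone, adjusted p = 0.46). GCLC (−1.05 ± 0.05) passed lower and GCLM (0.37 ± 0.08) higher. Of 7 basal genes (0 and 0 adjusted over the list alone, adjusted p = 0.29) KRT14, dim in both groups, rose, and of 12 stromal, endothelial and leukocyte markers (0 and 1 adjusted over the list alone, adjusted p = 0.46) COL3A1 fell by at least 1.20. CCNA2, DUSP1, FOXA2 and KRT14 no longer passed without DHT replicate 2 or without vehicle replicate 3 or 4, and CCNA2 and FOXA2 no longer passed with the mean of all probe sets. For the luminal, stromal and MYC lists the median, mean and test differed in sign.

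The DHT and siLSD1 calls in C42B, which share no arrays, were set side by side to ask whether genes that respond to the androgen also respond to the knockdown. Genes higher with both numbered 515 where independent lists would share 229 (Fisher's exact test, odds ratio 3.22, 95% interval 2.87 to 3.61). They were led by TRPM8 (at least 3.86 with DHT and 1.5 with siLSD1), LCK (at least 1.37 and 1.18), GREB1 (2.58 ± 0.09 and 1.27 ± 0.21), CRISP3 (1.21 ± 0.05 and 1.43 ± 0.08), SLC45A3 (3.83 and 1.19) and SEC24D (1.45 ± 0.10 and 1.12 ± 0.13). Genes lower with DHT and higher with siLSD1 numbered 595 (332 if independent, odds ratio 2.44, 2.19 to 2.72). Within strata of brightness and variance, added after seeing the data, these odds ratios were 2.55 (2.27 to 2.87) and 1.62 (1.45 to 1.80). All these intervals treat genes as independent, so they are narrower than the spread between cultures would allow. Genes lower with DHT and higher with siLSD1 included ACP3 (−1.61 ± 0.05 with DHT and 1.97 with siLSD1), SERPINI1 (−1.56 ± 0.05 and 1.69), TMEM178A (at least 0.02 lower with DHT and 1.76 higher with siLSD1), ARHGEF3 (−1.22 ± 0.07 and 1.27 ± 0.06), BLNK (−1.21 ± 0.06 and 1.06 ± 0.07) and MATN2 (−2.75 and 1.01 ± 0.10). Genes lower with both numbered 508 (359 if independent, odds ratio 1.66, 1.48 to 1.85), an excess not seen within strata (1.02, 0.915 to 1.14). Among them were RUNDC3B (at least 1.49 lower with DHT), NAV3 (−0.95 ± 0.08), PLPPR1 (−2.19 ± 0.05), UGT2B15, UGT2B17 and CCDC83 (−0.80 ± 0.06 with siLSD1).

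Genes higher with DHT and lower with siLSD1 numbered 260 against 248 for independent lists (odds ratio 1.06, 0.92 to 1.22, Fisher's exact p = 0.39), and were fewer than expected within strata (0.694, 0.602 to 0.80). IGF1 (1.73 ± 0.10 with DHT and −1.18 with siLSD1) led them, followed by ALPK2 (1.10 ± 0.07 and a fall of at least 0.50), the Mediator subunit MED30 (0.67 ± 0.04 and −0.77 ± 0.07), HSPA2 (at least 0.93 and −0.62 ± 0.08), RGS2 (0.61 ± 0.08 and −0.77 ± 0.05) and the prostaglandin receptor PTGER4 (at least 2.64 and −0.60 ± 0.08). Across all genes the log2 fold changes of the 2 comparisons had a Pearson correlation of 0.055 and a Spearman correlation of 0.023. Without C42B siLSD1 replicate 3 the counts were 314 for higher with both, 351 for lower with DHT and higher with siLSD1, 302 for lower with both and 148 for higher with DHT and lower with siLSD1. Without siLSD1 replicate 2 they were 335, 370, 331 and 168, and without siNTC replicate 2 the last 2 were 328 and 170.

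**Figure D4:**
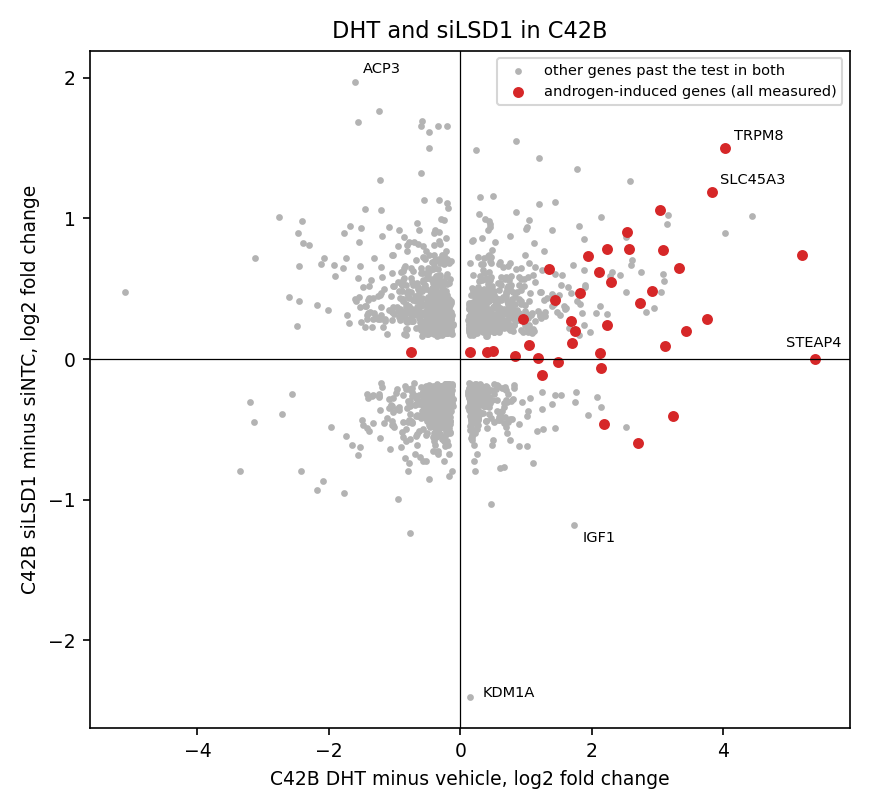
Log2 fold change with DHT (horizontal axis, 4 DHT and 4 vehicle arrays) against siLSD1 (vertical axis, 3 siLSD1 and 3 siNTC arrays) in C42B. Grey points are genes past the test in both comparisons and red points all 40 measured androgen-induced genes, of which 39 rose with DHT, 20 rose with siLSD1 and 3 fell with siLSD1. All 4 direction pairs hold many genes (515, 595, 508 and 260).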

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

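The tests of immune cells, of the siRNA itself and of stronger effects on all genes in LNCaP were chosen after the result was seen, and strata of brightness and variance after the shared calls but before the odds ratio within strata was seen.

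The siLSD1 effect differed between the lines, by the test of the difference itself, for 1100 genes above and 1200 below in C42B minus LNCaP. The lists that differed were DNA replication (median difference 0.58), mitosis (0.77), p53 targets (0.22), interferon-stimulated genes (−0.48), hypoxia and glycolysis (−0.21) and MYC and ribosome biogenesis (0.16). With an estimated correlation the last 2 no longer passed (adjusted p = 0.50 and adjusted p = 0.15). The genes were TM4SF1 (1.60), ZNF367 (1.52), S100P (−2.80), IFIT2 (−1.95), OASL (−1.85) and PYGL (−1.84). Fitted differences that rest on a dim group, and have no exact size or rank, were those of UGT2B28 (2.04, siLSD1 dim in C42B), CCDC83 (1.92) and MYBL1 (1.85, both with siLSD1 dim in LNCaP), TMEM178A (1.56, dim in both LNCaP groups), and CXCL10 (−2.03) and RSAD2 (−1.83), both dim in both C42B groups. As many genes passed in 6 of 100 splits of the siRNA labels within each line, with 2300 for the real labels and 6538 for the highest other, so chance is not excluded by this count. That highest split turns the labels of a single line and so adds the effects that the lines share, a structure of these samples. All 5 splits with as many genes, other than the real one, kept a line's true groups whole, and so kept that line's siRNA effect. The 85 splits that kept neither line whole reached at most 0, but they put the siRNA effects into the spread within groups. The splits therefore cannot decide whether the lines differ.

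In groups of 4 arrays, 8 of 232 sets of values (3.45%) had an array far from the others, where chance gives about 1 in 20. With DHT these were STEAP4 in replicate 4 (9.41, the others 9.53 to 9.55), RGS2 in replicate 2 (9.26, the others 9.0 to 9.03), MTA2 in replicate 1 (7.37, the others 7.57 to 7.61), KRT14 in replicate 3 (4.88, the others 4.55 to 4.56), SMS in replicate 4 (12.75, the others 12.58 to 12.61) and the actin 3′ minus 5′ signal in replicate 1 (1.16, the others 0.91 to 0.96). With vehicle they were the mean of the mitosis list in replicate 1 (10.62, the others 10.68 to 10.69) and the actin signal in replicate 4 (1.12, the others 0.90 to 0.93). The raised actin signals fell on 1 array of each group.

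Interferon-stimulated genes passed higher with siLSD1 in LNCaP at the preset correlation, but not with an estimated correlation (adjusted p = 0.17). The list also passed fry (adjusted p = 2.2e-04). A single array does not carry the rise, since the lowest siLSD1 list mean lay 0.68 above the highest siNTC mean. The wells held cultures of the LNCaP line, so the design offers no source of immune cells. The highest change plus 2 SE among stromal, endothelial and leukocyte markers was 0.39 against the list's median of 0.74. With 8 of the 12 markers dim, these values cannot decide the question by themselves. Transfection as such was shared, since the LNCaP siNTC cells also had 50 nM siRNA. A response to the sequence of the siLSD1 siRNA and a response to loss of LSD1 cannot be told apart, because each line has 1 siLSD1 label. The list's median of 0.042 in C42B came from another protocol and medium.

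Mitosis genes fell further in LNCaP than in C42B. Larger effects on all genes in LNCaP leave a median of −0.63 unexplained after scaling the C42B effects by 1.31, the slope over genes passing in both. The SE set against it, 0.087, is that of the list's means per array and leaves out the error of the slope. That slope was fitted to noisy C42B effects of genes that include mitosis genes. After quantile normalization of the 12 arrays 97.5% of the difference was kept, so it did not depend on the arrays' overall distributions. A constant offset between the experiments cancels in each line's effect before that step. Quantile normalization also cannot undo a scaling that differs between probe sets, so scaling as such is not excluded. Lower mitosis transcripts in C42B controls from the start cannot be told apart from other explanations. Their median was 0.34 above LNCaP controls after quantile normalization (SE of the list's means per array 0.031). The prediction overlooked that levels of separate experiments are not comparable. Line, medium, protocol, siRNA dose and labelling kit stay open as untested explanations.

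More genes passed with both DHT and siLSD1 in C42B than independent lists share. Brightness and precision explain part: within strata of both, the odds ratio of passing in both fell from 2.81 to 1.61 (95% interval 1.49 to 1.74). By direction pair it was 2.55 for higher with both, 1.62 for lower with DHT and higher with siLSD1, 1.02 (0.915 to 1.14) for lower with both, and 0.694 (0.602 to 0.80) for higher with DHT and lower with siLSD1. The excess of genes lower with both was therefore not seen within strata. The intervals treat genes as independent and do not measure the spread between cultures. A link between LSD1 and androgen-regulated genes may remain, as a hypothesis.

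For siLSD1, the 6 arrays of a line make 10 splits, too few for a share under 0.05. In C42B 1 of 10 splits gave as many genes as the real 3569 (highest other 0), and in LNCaP 1 of 10 gave as many as 5120 (highest other 0). For DHT 1 of 35 splits, the real one, gave as many as 6470 (highest other 0), the smallest share that 35 splits allow. Splits that mix the groups put the treatment effect into the spread within groups, which lowers their counts. The DHT count therefore does not exclude chance.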

How the results depend on the processing

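All alternatives whose effect on counts, lists and named genes is given here were chosen before the data were examined. The number of arrays and signal over background limit these results.

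KDM1A fell under every alternative run, by quantile normalization, median centring, a replicate block, all 20 arrays in 1 fit and leaving out each array, with ranges without single arrays of −2.48 to −2.36 in C42B and −2.84 to −2.70 in LNCaP. Another probe set of KDM1A could not be tried, since there is 1. The replicate block, which assumes a pairing that the values do not show, gave 1381 higher and 1407 lower genes with siLSD1 in C42B, 2575 and 2353 in LNCaP, 2468 and 3516 with DHT, and 978 and 1031 for the difference. With arrayWeights the difference between the lines had 1726 genes above and 1831 below. With median centring the larger direction changed, to 1694 higher and 1453 lower genes with siLSD1 in C42B, 2478 and 2639 in LNCaP, and 1188 above and 945 below for the difference, so which direction holds more genes depends on the scaling. Genes going opposite ways in the lines numbered 47 (higher in C42B) and 63 (lower in C42B) with all 20 arrays in 1 fit, and 22 (lower in C42B) with median centring. The cause was not tested.

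Leaving out single arrays, which leaves fewer samples, gave 958 to 1975 higher and 949 to 1987 lower genes with siLSD1 in C42B, the lowest without siLSD1 replicate 3 and the highest without siLSD1 replicate 1. It gave 670 to 1077 genes higher in both lines and 696 to 1064 lower in both, 13 to 49 higher in C42B alone with LNCaP lower, and 12 to 45 the other way. For DHT and siLSD1 in C42B it gave 314 to 547 higher with both, 148 to 268 higher with DHT and lower with siLSD1, 351 to 702 lower with DHT and higher with siLSD1, and 302 to 491 lower with both. The counts in LNCaP (1949 to 2955 and 1843 to 2689), with DHT (2253 to 2517 and 3262 to 3647) and for the difference (738 to 1483 and 821 to 1577) stayed within 1.5 times. Of 84 list tests 31 passed at the preset correlation, and with an estimated correlation 25 of these no longer passed and 6 did. None of the 6 came from the siRNA comparison of a single line, where few arrays leave that test few degrees of freedom. All 31 also passed fry, which asks about a list on its own. Among them were LNCaP mitosis (fry adjusted p = 2.9e-04), LNCaP interferon (2.2e-04) and C42B androgen-induced genes with siLSD1 (9.2e-05).

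Among named genes at least 1 other probe set gave the opposite sign for the values that follow, and among these only CTBP1 with DHT, CDK19 and SLC7A11 passed that way. With DHT they were ACKR3 (0.16), CCNA2 (0.0611), CSRNP3 (0.17), CTBP1 (1.09), FAS (0.0252), FOXA2 (−0.0206), HK2 (−0.0112) and IDI1 (−0.13 and −0.13). Next came KLK2 (−0.0347), MATN2 (0.0632), NAV3 (0.15), PLPPR1 (0.0825) and VIM (0.0052). With siLSD1 in C42B they were CLEC7A (−0.0896 and −0.0319), CNTNAP2 (−0.00997), CTBP1 (0.22), DUSP1 (−0.16 and −0.0181), GDF15 (−0.22), HMGCS1 (−0.18), KRT19 (−0.17) and LOX (0.0846). Next came MAF (−0.0793 and −0.0367), ME1 (−0.00479), MED30 (0.0419), OAS3 (0.0895), PGD (−0.19), REST (−0.15), SC5D (−0.18) and STOX2 (−0.15). With siLSD1 in LNCaP they were ATF3 (0.00593), CDK19 (0.33), COL3A1 (0.0344 and 0.13), DNAJC3 (−0.00305), EBP (0.14), EGR1 (−0.12), IGF1 (0.058) and KRT19 (−0.14). Next came LHX6 (−0.11), MYBL1 (0.21), SLC7A11 (−0.25), STOX2 (0.0114 and 0.21), TRPM8 (−0.17), TXNRD1 (0.0166) and UCHL1 (0.0671). For the difference between the lines they were TM4SF1 (−0.0148 and −0.12). The cause was not tested. Genes with probe sets passing in opposite directions numbered 58 with siLSD1 in C42B, 186 in LNCaP and 123 with DHT. Leaving out an array ended the call of 13 of 99 named genes in C42B, 11 of 89 in LNCaP, 4 of 91 with DHT and 0 of 12 for the difference. With the mean of all probe sets 16 named-gene results no longer passed: CCNA2 and FOXA2 with DHT, CNTNAP2, DUSP1, GDF15, HMGCS1, KRT19, LOX, PGD, REST, SC5D and TXNRD1 with siLSD1 in C42B, and ATF3, DNAJC3, DPYSL5 and LHX6 in LNCaP. REST and TXNRD1 in C42B also failed with median centring and the replicate block, TUBB3 in LNCaP and DUSP1 and KRT14 with DHT failed with the replicate block, and FOXA2 with DHT failed with quantile normalization and with trend and robust. COL3A1 with siLSD1 in C42B, which did not pass in the main fit, passed with the replicate block (limma adjusted p = 0.048).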

Other observations

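The gene families in this part were tested only after the data were seen; the tests of genes that DHT raised or lowered were chosen before their result was seen.

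Genes of the COPI and COPII coats, which move cargo between the ER and the Golgi, rose with DHT in 19 of 30 cases and fell in 2 (median 0.26, adjusted p = 3.2e-06, and adjusted p = 0.016 with an estimated correlation). With siLSD1 in C42B 8 rose and none fell (adjusted p = 0.0051, and adjusted p = 0.39 with an estimated correlation), while in LNCaP 6 rose and 3 fell and the family did not pass (adjusted p = 0.21). The coat genes did not pass for the difference between the lines either (camera adjusted p = 0.45). Metallothioneins, small metal-binding proteins, fell with DHT in 7 of 8 cases (median −0.42, adjusted p = 1.9e-04, and adjusted p = 0.37 with an estimated correlation) and rose with siLSD1 in LNCaP in 7 of 8 (0.32, adjusted p = 8.4e-04, and adjusted p = 0.26 with an estimated correlation), while none of 8 passed with siLSD1 in C42B. The difference between the lines had a median of −0.37 (adjusted p = 4.0e-04, and adjusted p = 0.070 with an estimated correlation). Aminoacyl-tRNA synthetases fell with DHT in 9 of 14 cases (−0.22, adjusted p = 0.0028, and adjusted p = 0.20 with an estimated correlation). The amino acid response list, which fell too (camera adjusted p = 7.3e-11, and adjusted p = 0.051 with an estimated correlation), itself holds the synthetases CARS1, WARS1 and AARS1. These results may therefore not be separate observations.

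With siLSD1, mitochondrial ribosomal protein genes fell in 21 of 77 cases in C42B (adjusted p = 1.8e-04, and adjusted p = 0.52 with an estimated correlation) and in 27 in LNCaP, with 1 higher (adjusted p = 3.9e-07, and adjusted p = 0.26 with an estimated correlation). Proteasome genes fell in 9 of 50 cases in C42B with 1 higher (adjusted p = 0.0024, and adjusted p = 0.45 with an estimated correlation) and in 18 in LNCaP with 2 higher (adjusted p = 3.2e-05, and adjusted p = 0.26 with an estimated correlation). HLA genes, which present antigen, rose in 8 of 22 cases in LNCaP with none lower (median 0.24, adjusted p = 8.4e-04, and adjusted p = 0.30 with an estimated correlation). Other families passed at the preset correlation but not with an estimated one (adjusted p = 0.069 to 0.62). They were tetraspanins with siLSD1 in C42B (adjusted p = 0.047) and LNCaP (adjusted p = 0.027), UGT2B and UGT1A genes in LNCaP (adjusted p = 1.8e-04) and for the difference (adjusted p = 4.8e-04), and HLA genes for the difference (adjusted p = 0.0011). With DHT they were zinc finger (adjusted p = 0.0028), mitochondrial ribosomal protein (adjusted p = 0.021) and complex I genes (adjusted p = 0.013). The scaling alternatives were not run on these families.

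A hypothesis was that LSD1 holds down genes that androgen raises. The 230 genes that DHT raised at least 2-fold had a median of 0.22 with siLSD1 in C42B (111 higher, 23 lower, adjusted p = 2.4e-17, and adjusted p = 0.034 with an estimated correlation). In LNCaP it was 0.19 (96 higher, 31 lower, adjusted p = 9.5e-06, and adjusted p = 0.071 with an estimated correlation). The 231 genes that DHT lowered at least 2-fold also lay higher with siLSD1, at 0.12 in C42B (83 higher, 44 lower, adjusted p = 3.4e-05, and adjusted p = 0.29 with an estimated correlation) and 0.093 in LNCaP (87 higher, 44 lower, adjusted p = 0.0093, and adjusted p = 0.32 with an estimated correlation). So both sets may respond to siLSD1 in the same direction, though with an estimated correlation only the raised set in C42B passed, and the sets were not tested against each other. Of the raised set 34 genes, and of the lowered set 3, are on the androgen-induced or androgen-repressed list.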
